A study of Mus musculus with 12 samples.

How the data were processed

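Poly(A) RNA of mouse peritoneal macrophages was sequenced in 12 libraries, 3 in each of 4 groups. Per the labels, the cells came from 8-week-old male mice, 3 days after an intraperitoneal injection of 3% Brewer thioglycolate, which draws monocytes and other cells into the peritoneum. Libraries labelled Ern1fl/fl are called WT and libraries labelled Mac-Ern1KO are called KO. In the R300 groups the cells had spent 2 h with platelets coated with R300, an antibody to the platelet protein CD42. In the blank groups the labels give the treatment as Con and do not say whether platelets without antibody or no platelets were added. The Cre driver that deletes Ern1 is not named in the labels. Per the labels' protocols, mRNA was enriched on oligo(dT) beads and libraries were made with a NEBNext Ultra kit, which does not mark the strand.

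Per the submitters' processing notes, FastQC 0.12.1, fastp 0.23.4, HISAT2 (version given as 2), featureCounts 2.0.3 and DESeq2 1.42.0 were used with the mm10 genome. The deposited values were raw counts per gene symbol, in a table of 35050 rows by 12 libraries. The columns were identical to the 12 sample files. Rows without a symbol numbered 102 and held 0.0232% to 0.0328% of each library's counts; they were left out of the tests. Another 18 symbols had more than 1 row (38 rows in all). The notes do not say how reads on overlapping genes of opposite strands were counted, so a gene that overlaps another on the opposite strand can hold some of its neighbour's reads. Totals, to 6 digits, ran from 21765600 to 44273700 counts per library. Positions come from the GENCODE annotation of GRCm38, the assembly that mm10 names.

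Counts were tested with edgeR 4.0.16 (TMM normalisation, filterByExpr with the 4 groups, robust quasi-likelihood fit) in R 4.3.3. The fit held all 12 libraries and 1 mean per group, and 16546 genes were tested. Benjamini-Hochberg adjusted p under 0.05 was called. The common biological coefficient of variation was 0.267. Comparisons were blank KO with blank WT, R300 WT with blank WT, R300 KO with blank KO, R300 KO with R300 WT, and the difference of the R300 responses (KO minus WT, the interaction term). Expression values are TMM-normalised CPM, with the SD over 3 libraries, and log2 fold changes have the standard error (SE) of the fit. For single values, 3 libraries against 3 cannot give an exact two-sided permutation p under 0.1.

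The tests, the samples, the alternatives, the rule for named genes and 36 gene lists were fixed before the data were examined. The lists cover the unfolded protein response (XBP1 targets, substrates of IRE1-dependent decay, the ATF4 program, ATF6 chaperones), the degradative and uptake machinery (lysosome, V-ATPase, autophagy, Fc receptor phagocytosis, scavenger and apoptotic cell receptors) and the circadian clock with genes described as repressed by NR1D1. Response lists cover inflammatory, immediate early, interferon, alternative activation, cholesterol synthesis, lipid efflux, NRF2 and heme, glycolysis and hypoxia, oxidative phosphorylation, NADPH oxidase, antigen presentation and cell cycle genes. Lists for other cells cover platelets, erythroid cells, neutrophils, eosinophils and mast cells, B cells, T and NK cells, dendritic cells, resident peritoneal macrophages, recruited monocytes, and mesothelial cells and fibroblasts. Quality lists cover mitochondrially encoded, heat shock and ribosomal protein transcripts. The list of IRE1 substrates includes Nr1d1 because the title of the series names it. Lists were tested with camera of limma 3.58.1 on voom values (preset correlation 0.01, adjusted over the 36 lists of a comparison), and again with an estimated correlation and with fry. A list is called at adjusted p under 0.05 with the preset correlation. No list call of the 5 comparisons held with an estimated correlation or with fry after adjustment.

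Named genes are Ern1, Xbp1 and Nr1d1 in every comparison. The others are the 6 largest called changes in each direction, among genes with a mean count of at least 20, libraries that did not overlap between the groups and a symbol that is not a clone or predicted name. To these the rule adds the 3 members with the lowest p in the direction of each called list, and the 2 members with the lowest p of the lists on the unfolded protein response, degradation and uptake, the clock and NR1D1. Lyz2, Eps8l1, H2-M3, H2-Q5, Pde4d, Cdkn1a and Ptger4 fall outside the rule and were chosen after their values were seen. Not every gene that the rule names is given, and the result of 1 of them is withheld.

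Alternatives fixed beforehand were the DESeq2 1.42.0 Wald test, relative log expression size factors, library totals only, no filter on low counts, only the groups compared, a replicate block, a minimum fold of 2, and each of the 12 libraries left out in turn. Another 6 were chosen after seeing the data: a batch term for the 4 libraries without Xist, the share of XX cells estimated from Y-linked transcripts as a covariate, only the 8 libraries with Xist, both blank libraries numbered 2 set aside, 1 library of each near-identical R300 pair set aside, and a replicate block for the blank libraries only. The last was chosen because deviations from the group means correlated between blank WT and blank KO libraries of the same number (0.514, 0.535 and 0.558 for numbers 1, 2 and 3; -0.366 to -0.158 between different numbers). This pairing comes from the counts, not from the labels, and both libraries numbered 3 lack Xist. No other 2 groups were paired by number in all 3 cases. Blank and R300 libraries of a genotype whose deviations from their group means correlated above 0.3 across genes were joined into apparent pools of mice, also after seeing the data. Libraries of different genotypes were never joined, though their correlations were as high (0.642 for WT R300 2 with KO R300 3). The apparent pools may therefore reflect something other than shared mice. The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For the R300 WT comparison 41 and 78 of them were called, with 6 false calls among 16264 genes. The simulated R300 KO comparison held no change and gave 0 calls. A simulated list of 30 shifted genes had an adjusted p of 2.33e-14, and 0 of 20 random lists were called. Simulated genes and libraries were drawn independently, without correlation between genes and without pools. The simulation therefore does not show how often genes or lists are called falsely where such correlation or pools exist.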

Results

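Bulk RNA sequencing measured transcripts in peritoneal macrophages of 2 genotypes, with and without 2 h of contact with antibody-coated platelets. The 4 groups, blank WT, R300 WT, blank KO and R300 KO, held 3 libraries each. Total counts, to 6 digits, ran from 21765600 (WT blank 1) to 44273700 (KO blank 2). The title of the series asks how IRE1α, the endoplasmic reticulum (ER) stress sensor that Ern1 encodes, bears on phagocytosis through decay of Nr1d1 mRNA and the making of lysosomes. The comparisons ask what coated platelets change in macrophages of each genotype, what loss of Ern1 changes in each state, and whether the response differs between genotypes.

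The libraries differed in composition within every group. Although the labels give male mice, 8 libraries held 143 to 590 CPM of Xist, the transcript that silences an X chromosome in female cells. The other 4 (WT blank 3, WT R300 2, KO blank 3 and KO R300 3, 1 in each group) held at most 0.0742 CPM. The sum of the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y was 42.6 to 162 CPM in the libraries with Xist and 205 to 224 CPM in those without. The share of XX cells estimated from Y-linked transcripts was not balanced between the genotypes. In R300 it was 77.9% and 77.4% in KO 1 and 2, against 24.9% and 30.5% in WT 1 and 3. In blank cells it was 80.3% and 66.9% in KO 1 and 2, against 31.0% and 67.8% in WT 1 and 2. In the libraries with Xist, differences between genotypes therefore cannot be told apart from sex composition. The 4 without Xist had estimated shares of -3.57% to 5.17%. Among them Lyz2 was 6780 and 6888 CPM in KO against 12845 and 12729 CPM in WT. The mean of the interferon list differed by -0.868 log2 units (KO minus WT). For Lyz2 and this list, these values argue against sex composition as the only source. Those libraries are 1 apparent pool of each genotype, so other differences between pools stay open. Some R300 libraries were nearly alike. WT R300 1 and 3 differed by a median chi-square of 1.45 per gene and KO R300 1 and 2 by 1.65, against 7.89 to 14.0 for the other pairs of libraries within a group. Each of these near-alike pairs fell in 1 apparent pool, so an R300 group may hold fewer than 3 independent samples. For the R300 groups, n = 3 counts libraries, and the SD and p may understate the spread between mice. The mix of apparent pools also differed between blank and R300. WT blank 2 and KO blank 2 have no R300 library in their apparent pools, and each near-alike pair makes up 2 of the 3 libraries of its R300 group. The tests did not block on the apparent pools, so a difference between R300 and blank can also reflect this mix.

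**Figure D1:**
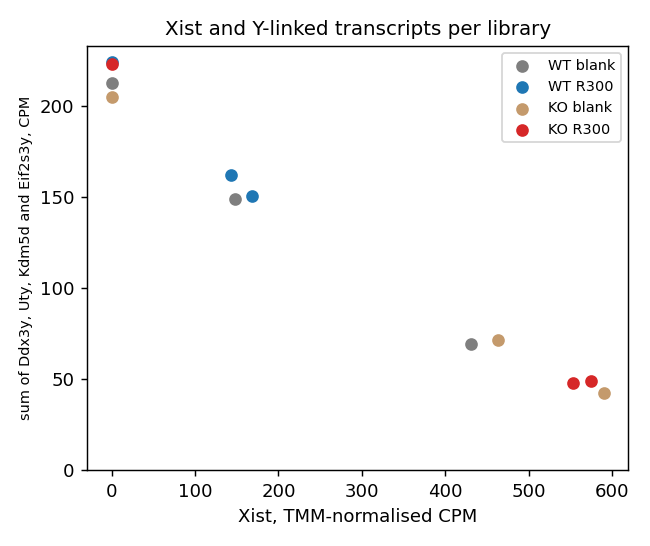
Xist (horizontal axis, TMM-normalised CPM) against the sum of 4 Y-linked genes (vertical axis, CPM) in the 12 libraries, 1 point per library, coloured by group. The 4 libraries with almost no Xist lie at 205 to 224 CPM of Y-linked transcripts and the 8 others at 42.6 to 162 CPM.

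Ern1 was not lower in the libraries labelled KO. Its level was 113, 117 and 94.1 CPM in WT blank 1 to 3, 204, 138 and 205 CPM in WT R300, 150, 155 and 116 CPM in KO blank, and 235, 225 and 174 CPM in KO R300. The log2 difference of KO from WT was 0.38 (SE 0.18, n = 3, adjusted p = 1.00) in blank cells and 0.21 (SE 0.18, adjusted p = 1.00) in R300 cells. Counts summed over a whole gene do not show whether a floxed exon is missing from its mRNA, so these values check neither the deletion nor the labels. Ern1 lies on chromosome 11 at 106394650 to 106487852 of GRCm38.

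With R300, Ern1 was 1.69-fold its blank level in WT (log2 0.75, SE 0.18, adjusted p = 0.136) and 1.51-fold in KO (log2 0.59, SE 0.18, adjusted p = 0.244), which did not pass. The WT change passed with DESeq2 (adjusted p = 0.0168) and without WT R300 2 (adjusted p = 0.0374). With a batch term for the libraries without Xist, adjusted p was 0.000652 in WT and 0.00160 in KO. Over all alternatives it ran from 0.000652 to 0.754 in WT and from 0.00160 to 0.867 in KO. Nr1d1, a circadian repressor of transcription, was 9.24 ± 1.83 CPM (SD, n = 3) in WT blank, 6.27 ± 1.08 in WT R300, 10.3 ± 1.49 in KO blank and 10.4 ± 1.59 in KO R300. Its log2 change with R300 was -0.56 in WT (SE 0.20, adjusted p = 0.420; 0.0298 with the batch term, the lowest of its alternatives) and 0.01 in KO (SE 0.20, adjusted p = 1.00). In R300 cells Nr1d1 was 1.65-fold higher in KO than in WT (log2 0.73, SE 0.20, adjusted p = 1.00). The difference of its R300 responses was 0.57 (SE 0.29, adjusted p = 1.00). Over both treatments, an exact permutation of genotype within treatment gave p = 0.03 for Nr1d1, 0.065 for Ern1 and 0.62 for Xbp1. These p are unadjusted, and libraries that share an apparent pool are not independent, so they may be too small. Nr1d1 lies on chromosome 11 at 98767932 to 98775333, and 8.55% of its exonic bases overlap Thra on the opposite strand. Xbp1, whose mRNA IRE1α splices, had log2 differences of -0.14 (blank KO against WT), 0.14 and 0.33 (R300 in WT and KO) and 0.05 (R300 KO against WT), with no adjusted p under 0.566. Xbp1 lies on chromosome 11 at 5520659 to 5525893, and counts per gene do not separate its spliced form.

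**Figure D2:**
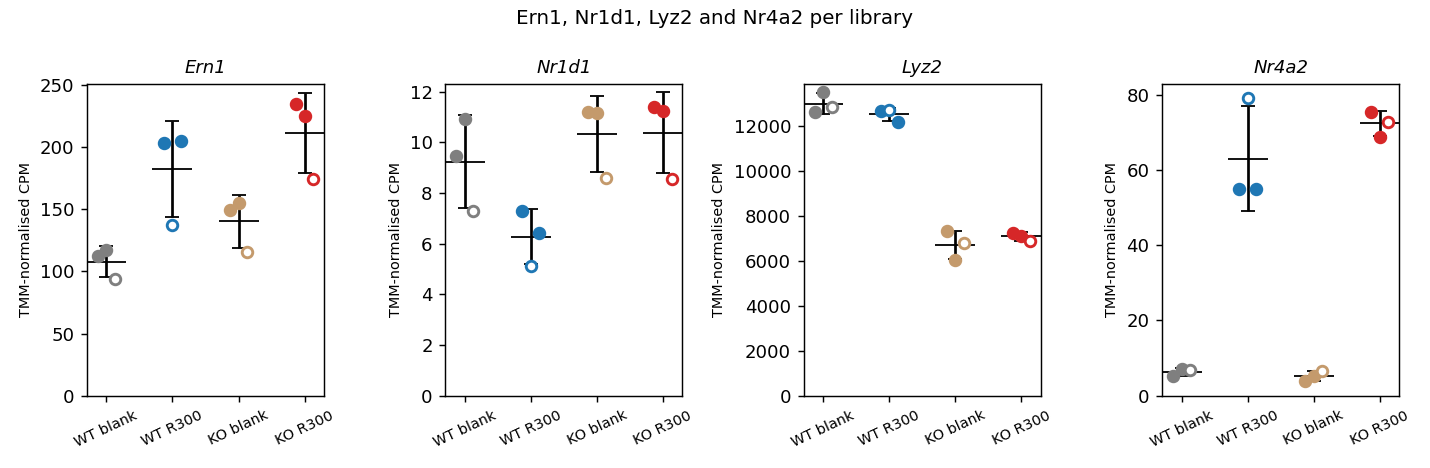
TMM-normalised CPM (vertical axes, from 0) of Ern1, Nr1d1, Lyz2 and Nr4a2 per library in the 4 groups. Each circle is a library (open circles mark libraries without Xist) and the bars give the mean ± SD of 3; Lyz2 lies at 12183 to 13522 CPM in WT and 6058 to 7317 CPM in KO.

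In WT macrophages, nuclear receptors of the NR4A family, the cyclic AMP repressor Crem and the angiogenic factor Vegfa were higher with R300 than in blank cells. The labels give 2 h of co-culture for the R300 groups only and do not say whether blank cells received platelets. Antibody coating, platelets and time in culture therefore cannot be told apart as the source of the R300 changes. Nr4a2 rose 9.96-fold, from 6.31 ± 0.973 to 63.1 ± 14.0 CPM (SD, n = 3; log2 3.32, SE 0.22, adjusted p = 0.000103). Crem rose 11.6-fold (log2 3.54, SE 0.37), Vegfa 8.91-fold (log2 3.15, SE 0.32), Cbarp 7.77-fold (log2 2.96, SE 0.30), Nr4a3 5.06-fold and Nr4a1 4.85-fold. Thbs1, which encodes the matrix and platelet protein thrombospondin 1, rose 10.9-fold (log2 3.45, SE 0.56), and Tlr5, the flagellin receptor, rose 11.8-fold to 5.18 ± 3.07 CPM. Thbs1 reached 20706 and 20404 CPM in WT R300 1 and 3 and 7452 CPM in WT R300 2, the library without Xist. Among the genes that fell, the potassium channel gene Kcnj2 dropped to 0.125 of its blank level (log2 -3.00, SE 0.37). Ciita, the master regulator of MHC class II genes, fell to 0.425 (log2 -1.24, SE 0.20), and Rassf4, Il20rb, Tifa and Ypel2 fell to 0.466, 0.489, 0.525 and 0.528. Of 16546 genes, 103 passed (91 higher, 12 lower), 70 of them at least 2-fold. Of the genes, 1442 had an unadjusted p under 0.05, where 827 are expected by chance, and the groups did not overlap for 12.8% of genes, where chance gives 10%. DESeq2 called 355 genes, 73.5% of them higher, against 88.3% with edgeR.

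Calls for Nr4a2, Nr4a3, Crem, Vegfa, Cbarp and Kcnj2 in WT held without any 1 of the 12 libraries. The Thbs1 call was lost without any WT library except R300 2 (adjusted p 0.0877 to 0.108), and the Nr4a1 call without WT blank 2, R300 1 or R300 3 (0.0712 to 0.0901). Those of Ciita and Rassf4 were lost without WT blank 1, WT blank 2, WT R300 1 or WT R300 3, and that of Rassf4 also without KO R300 1 or 2 (0.0619 to 0.192 for both genes). The Tlr5 call was lost without any WT library except R300 2 and without KO blank 3, KO R300 1 or KO R300 2 (0.0509 to 0.144). Il20rb kept its call only without KO blank 3 or KO R300 3, Tifa only without KO blank 1 or KO blank 2, and Ypel2 only without WT blank 1, KO blank 2 or KO blank 3 (otherwise 0.0536 to 0.246 for the 3 genes). The number of called genes was 33, 45 and 56 without WT blank 1, 2 and 3, 32 without WT R300 1 or 3, and 60 and 55 without KO R300 1 and 2. It was 347 with a batch term for the libraries without Xist, 242 in the 8 libraries with Xist, and 28 with 1 library of each near-identical R300 pair.

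Immediate early genes were among the called groups in WT. Of 33 measured, 4 rose and none fell (8 and 1 adjusted over the list alone), the NR4A genes among them, and the list had an adjusted p of 5.05e-05. In the glycolysis and hypoxia list, 2 of 32 rose (3 adjusted over the list alone). They were Vegfa and Slc2a1, the glucose transporter GLUT1, at 1.83-fold (log2 0.87, SE 0.10). The lactate exporter Slc16a3 was at 2.09-fold without passing (adjusted p = 0.213). In the alternative activation list 3 of 26 rose (4 adjusted over the list alone). Besides Vegfa these were the transglutaminase Tgm2 (2.33-fold, log2 1.22, SE 0.20) and Clec7a, the receptor for fungal glucans (2.11-fold, log2 1.07, SE 0.19). In the heat shock list, a sign of cell handling, 1 of 18 rose, Hsph1 at 1.63-fold (log2 0.70, SE 0.12). Adjusted p of the 4 lists was 5.05e-05 to 0.0337, and 0.577 to 0.700 with an estimated correlation. The Tgm2 and Clec7a calls were lost without any WT library except R300 2 and without KO R300 2, that of Clec7a also without KO blank 1 or KO R300 1 (0.0518 to 0.188). The Hsph1 call was lost without any WT library except blank 3 and without KO R300 2 (0.0543 to 0.146). The alternative activation call ended without WT blank 3, WT R300 1, WT R300 3 or KO blank 2 (0.0518 to 0.285).

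Smaller shifts ran through other lists in WT. In the ATF4 program of amino acid and stress genes, 19 of 29 values were negative (median log2 -0.23, adjusted p = 0.0207; 0.790 with an estimated correlation). Of its members, 1 rose and 1 fell adjusted over the list alone and none over all genes. They were Ddit4 at 4.10-fold (adjusted p = 0.0786 over all genes) and Atf3, a stress-induced repressor, at 0.566 (adjusted p = 0.139). Atf3 passed without KO blank 1 (0.0227) or KO blank 2 (0.0470), and Ddit4 without WT R300 2 (0.0266) or KO R300 3 (0.0338). Among XBP1 targets, 28 of 39 were positive (median 0.09, adjusted p = 0.0337; 0.670 with an estimated correlation), with Ostc at 1.14-fold and Dnajb11 at 1.11-fold. For oxidative phosphorylation 36 of 41 were positive (median 0.08, adjusted p = 0.0107; 0.700), with Atp5d at 1.20-fold, and for cell cycle genes 31 of 35 (median 0.30, adjusted p = 0.0176; 0.822), with Cenpa at 1.83-fold. No member of these 3 lists passed alone. The XBP1 call ended without any WT library except blank 2 (0.0501 to 0.129), and the ATF4 call without WT blank 2 (0.227) or WT R300 2 (0.190). The oxidative phosphorylation call ended without WT blank 1, WT R300 1 or WT R300 2 (0.0549 to 0.0681), and the cell cycle call without WT blank 2, WT blank 3, WT R300 1 or WT R300 3 (0.0622 to 0.763).

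Markers of other cells moved alongside these groups in WT. All 20 measured B cell markers were lower with R300 (median log2 -0.96, adjusted p = 4.26e-05; 0.670 with an estimated correlation), with Ms4a1 at 0.335 and Cd79b at 0.371 of the blank level. The call rested on WT blank 2 (adjusted p = 0.461 without it). Of 16 markers of recruited monocytes 15 were lower (adjusted p = 0.00798; 0.670), with Cx3cr1 at 0.324, the member that fell adjusted over the list alone, and Ccr2 at 0.408. This call also ended without WT blank 2 (0.465), and Gpr141 at 0.387 passed only without WT R300 2 (0.0482). Eosinophil and mast cell markers were higher, 1 of 13 rising over all genes and 5 adjusted over the list alone (adjusted p = 3.95e-05; 0.577). That member was Gata2, a transcription factor of blood progenitors and mast cells, at 4.29-fold (log2 2.10, SE 0.22), beside Mcpt4 at 3.02-fold and Tpsb2 at 2.04-fold. The Gata2 and list calls held without any 1 library. Of 17 mesothelial and fibroblast markers 16 were positive (median 1.15, adjusted p = 0.00224; 0.700), with Sparc at 2.25-fold, and the call ended without WT R300 3 (0.132). All 15 mitochondrially encoded transcripts were lower (median -0.25, adjusted p = 0.0439; 0.855). That direction turned without WT blank 2 (mean log2 0.08, adjusted p = 0.259), and the call also ended without WT R300 1 (0.151), WT R300 3 (0.132) or KO blank 2 (0.0692).

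In macrophages labelled KO, much the same leading genes were higher with R300 than in blank cells. Nr4a2 rose 13.9-fold, from 5.19 ± 1.38 to 72.4 ± 3.33 CPM (SD, n = 3; log2 3.80, SE 0.22, adjusted p = 4.25e-05). Crem rose 14.5-fold (log2 3.86, SE 0.37), Vegfa 11.4-fold (log2 3.51, SE 0.33), Thbs1 9.67-fold (log2 3.27, SE 0.56), Nr4a1 5.75-fold and Nr4a3 3.68-fold. The cytokine gene Osm rose 10.4-fold (log2 3.38, SE 0.63) and the microRNA gene Mir132 9.71-fold, to 1.17 ± 0.277 CPM. Thbs1 and Osm were lower in KO R300 3, the library without Xist (9859 and 77.1 CPM), than in KO R300 1 and 2 (34492 and 30485 CPM for Thbs1, 381 and 336 CPM for Osm). Kcnj2 fell to 0.0940 of its blank level (log2 -3.41, SE 0.38), Depp1 to 0.165, Rnd3, which encodes a small GTPase of the actin skeleton, to 0.314, Ciita to 0.413, Rassf4 to 0.431 and Atf3 to 0.452 (log2 -1.15, SE 0.20). In all, 138 genes passed (115 higher, 23 lower), 85 of them at least 2-fold. An unadjusted p under 0.05 was reached by 1452 genes, and the groups did not overlap for 12.3%, where chance gives 10%. DESeq2 called 438 genes, 70.5% of them higher against 83.3% with edgeR, and scaling by library totals alone gave 86 higher and 32 lower (72.9%).

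Calls for Nr4a2, Nr4a3, Crem, Vegfa, Mir132 and Kcnj2 in KO held without any 1 of the 12 libraries. The Nr4a1 call was lost without KO R300 1 (adjusted p 0.0528), and that of Thbs1 without KO blank 2, KO blank 3, KO R300 1 or KO R300 2 (0.0879 to 0.105). Those of Ciita and Rassf4 were lost without KO blank 1, KO R300 1 or KO R300 2, and that of Rassf4 also without KO blank 2 (0.0590 to 0.106). The Atf3 call was lost without WT R300 1 or 3, KO blank 2 or 3, or any KO R300 library (0.0528 to 0.148). That of Rnd3 was lost without WT blank 1, WT R300 1 or 3, KO blank 1 or 2, or any KO R300 library (0.0572 to 0.189). Osm kept its call only without WT blank 1, WT R300 2 or KO R300 3, and Depp1 only without KO R300 3 (otherwise 0.0510 to 0.213). The number of called genes was 81 and 85 without WT R300 1 and 3, 59 and 86 without KO blank 1 and 3, and 45 without KO R300 1 or 2. It was 450 with a batch term for the libraries without Xist, 290 in the 8 libraries with Xist, and 34 with 1 library of each near-identical R300 pair.

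Immediate early genes were called in KO too. Of 33 measured, 4 rose and 1 fell (9 and 1 adjusted over the list alone), with an adjusted p of 1.56e-05 and 0.717 with an estimated correlation. The ATF4 program was lower, with 24 of 29 values negative (median log2 -0.45, adjusted p = 1.56e-05; 0.717 with an estimated correlation). Of its members 1 rose and 1 fell (1 and 5 adjusted over the list alone). Atf3 fell, Chac1 (0.211 of blank, adjusted p = 0.191) and Nupr1 (0.468, adjusted p = 0.242) did not pass, and Ddit4, an inhibitor of mTORC1, rose 4.41-fold (log2 2.14, SE 0.42). In the NRF2 and heme list 2 of 31 rose (3 adjusted over the list alone; adjusted p = 0.00330; 0.717 with an estimated correlation). These were Gclc, which makes glutathione (1.91-fold, log2 0.93, SE 0.14), and the antioxidant enzyme gene Srxn1 (1.81-fold, log2 0.85, SE 0.14). The same 2 genes rose in WT, where the list was not called (adjusted p = 0.121). Interferon-stimulated genes were lower in 38 of 42 cases (median -0.38, adjusted p = 3.18e-05; 0.856), with none passing alone and Gbp5 at 0.352 and Parp14 at 0.655. The ATF4, immediate early and interferon calls held without any 1 library. The interferon mean did not fall from KO blank 3 (4.63 log2 CPM) to KO R300 3 (4.70), which share an apparent pool. In another apparent pool it was 3.93 in KO blank 1 and 3.49 and 3.63 in KO R300 1 and 2. KO blank 2, at 4.70, has no R300 library in its apparent pool. For this list, an R300 effect therefore cannot be told apart from a different mix of apparent pools. Ddit4 kept its call only without WT R300 2 or KO R300 3 (otherwise 0.0627 to 0.213), Gclc lost it without KO R300 1 (0.0578) or 2 (0.0652), and Srxn1 without any KO library except R300 3 (0.0579 to 0.103). The NRF2 and heme call ended without KO blank 2 (0.0553) or KO R300 1 (0.0545).

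Metabolic and activation lists moved as well in KO. In the glycolysis and hypoxia list 2 of 32 rose (3 adjusted over the list alone; adjusted p = 0.0189), Vegfa and Slc2a1 (1.92-fold, log2 0.94, SE 0.10), beside Slc16a3 at 2.58-fold (adjusted p = 0.0721). In the alternative activation list 3 of 26 rose (4 adjusted over the list alone; adjusted p = 0.0258), among them Tgm2 (2.39-fold, log2 1.26, SE 0.20) and Clec7a (2.45-fold, log2 1.29, SE 0.19). For oxidative phosphorylation 33 of 41 were positive (median 0.06, adjusted p = 0.0206), with none passing alone and Atp5d at 1.16-fold. In the heat shock list 1 of 18 rose (2 adjusted over the list alone; adjusted p = 0.0126), Hsph1 at 1.64-fold. Adjusted p with an estimated correlation was 0.717 to 0.833 for these 4 lists. Without KO R300 3, Slc16a3 (0.0262) and Hspa8 (0.0300) passed too. Tgm2 lost its call without KO blank 1, KO blank 3, KO R300 1 or KO R300 2, Clec7a without KO blank 1, KO R300 1 or KO R300 2, and Hsph1 without KO blank 1, KO blank 2 or KO R300 2 (0.0533 to 0.103). Slc2a1 kept its call without any 1 library. The glycolysis call ended without KO blank 1, KO blank 3, KO R300 1 or KO R300 2 (0.0545 to 0.129), and the alternative activation call without KO blank 3, KO R300 1 or KO R300 2 (0.0592 to 0.355). The oxidative phosphorylation call ended without KO blank 1, KO R300 1 or KO R300 3 (0.0745 to 0.710), and the heat shock call without KO blank 3 (0.129) or KO R300 2 (0.0797).

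Of the markers of other cells in KO, 19 of 20 for B cells were lower with R300 (median log2 -0.65, adjusted p = 0.000424; 0.833 with an estimated correlation), with Fcer2a at 0.221. Fcer2a was at 0.464 to 1.48 CPM in blank KO and 0.103 to 0.318 CPM in R300 KO, so its ratio rests on few counts. The B cell call ended without KO blank 2 (0.179) or KO R300 3 (0.0622). Eosinophil and mast cell markers were higher in 10 of 13 cases (adjusted p = 0.000677; 0.717). Gata2 rose 4.06-fold (log2 2.02, SE 0.22), the only member to pass, and Cpa3 stood at 1.92-fold. The Gata2 and list calls held without any 1 library.

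**Figure D3:**
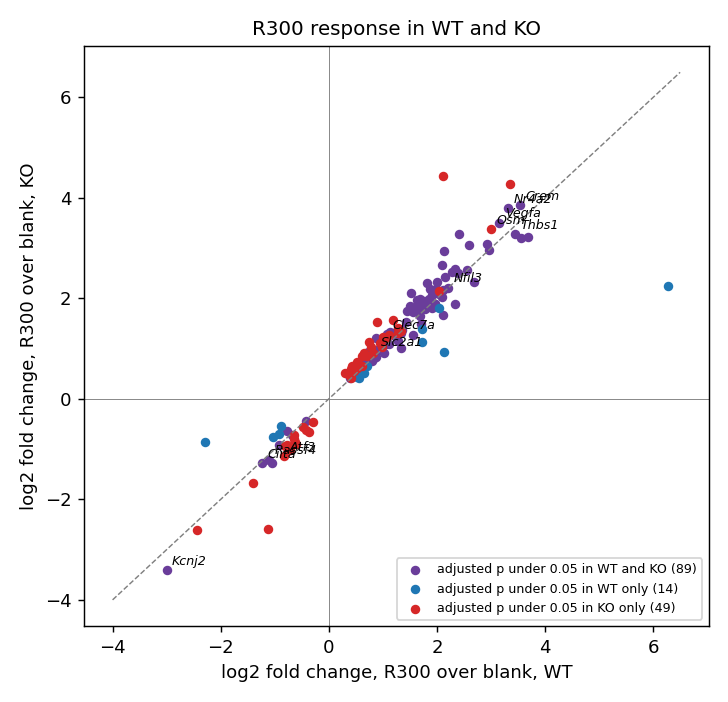
Log2 fold change of R300 over blank in WT (horizontal axis) and KO (vertical axis), 1 point per called gene, coloured by the genotype of the call. Genes called in neither genotype are not drawn. The 89 genes called in both genotypes, the 14 in WT and the 49 in KO lie on the same side of 0 on both axes.

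The R300 responses of the genotypes overlapped. Both held 81 of the higher genes, where independent lists would share 0.632, and 8 of the lower genes, where they would share 0.0167. The lists are not independent, since deviations from the group means correlated between genotypes. The correlation was 0.514 to 0.558 for blank libraries of 1 number and 0.642 for WT R300 2 with KO R300 3. An overlap above the independent values is thus no proof of a shared response. The 103 WT calls had the same sign in KO and the 138 KO calls the same sign in WT. Log2 changes correlated across genes with r = 0.676. Shared deviations can raise r too, and genes are not independent replicates. The difference of responses passed for 0 genes with edgeR (95 at an unadjusted p under 0.05) and for 0 with DESeq2 (97). Phagocytic and scavenger receptor lists were not called in either response (adjusted p 0.0837 to 0.602). Their members Clec7a and Havcr2, which encodes TIM-3, rose in both, Havcr2 2.57-fold in WT (log2 1.36, SE 0.18) and 2.58-fold in KO (log2 1.37, SE 0.18). The WT call of Havcr2 was lost without WT blank 1 (0.0544). Fcgr3, an Fc receptor for IgG, was at 1.56-fold in KO (adjusted p = 0.0864) and the actin nucleator Arpc3 at 1.48-fold (adjusted p = 0.0852); both passed without KO R300 3 (0.0305 and 0.0409). Of the platelet markers, 12 of 16 were positive with R300 in WT (median 0.37, adjusted p = 0.157; 0.0279 with the batch term) and 9 of 16 in KO (adjusted p = 0.409).

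Camera called 6 lists for the difference of the responses, each with an adjusted p of 0.991 with an estimated correlation. Interferon-stimulated genes had the lower response in KO in 41 of 42 cases (mean log2 -0.32, adjusted p = 4.70e-07), with Ifi44 at -1.01 (SE 0.64), as did 24 of 29 genes of the ATF4 program (mean -0.20, 0.0195), with Shmt2 at -0.33, a gene of serine metabolism. So did 32 of 35 cell cycle genes (mean -0.24, 0.0207), 11 of 13 eosinophil and mast cell markers (mean -0.36, 0.0207) and 15 of 17 mesothelial markers (mean -0.52, 0.0195). All 15 mitochondrially encoded transcripts had the higher one (mean 0.22, 0.0306). No member of these lists passed, and each call ended without some single library. The interferon call ended without WT blank 2, WT R300 2 or KO R300 1 (0.0666 to 0.231), and the ATF4 call without WT blank 1, WT blank 3, WT R300 1, KO blank 2 or KO R300 1 (0.0800 to 0.332). The eosinophil and mast cell call ended without WT blank 1, WT R300 3, KO blank 2 or KO R300 3 (0.0948 to 0.612), and the mitochondrial call without WT blank 2, WT R300 1, WT R300 3, KO blank 1 or KO R300 3 (0.182 to 0.813). The cell cycle and mesothelial calls ended without WT blank 2, WT blank 3, WT R300 1, WT R300 3, KO blank 1, KO R300 1 or KO R300 3 (0.0713 to 0.949). Signs turned for ATF4 without KO blank 2 (mean 0.10), for cell cycle (0.03) and mesothelial genes (0.09) without WT R300 3, and for mitochondrial transcripts without WT blank 2 (mean -0.10). The interferon mean was -0.02 without WT R300 2 and 0.01 with both blank libraries numbered 2 set aside (adjusted p = 0.915).

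In blank cells, the clearest difference of the libraries labelled KO from WT was in Lyz2, the lysozyme gene of myeloid cells. It was lower by a log2 difference of -0.95 (SE 0.12, n = 3), and each of the 6 KO libraries (6058 to 7317 CPM) lay below each of the 6 WT libraries (12183 to 13522 CPM). Its adjusted p was 0.0779, the smallest of this comparison, and 0 of 16546 genes passed with edgeR; 181 had an unadjusted p under 0.05, where 827 are expected by chance. Groups did not overlap for 3.70% of genes, where chance gives 10%. The blank libraries of WT and KO deviate together by number, which an unpaired test ignores. With their number as a block 0 genes passed, Lyz2 had an adjusted p of 0.121 and 342 genes an unadjusted p under 0.05, and 24.8% of genes went 1 way in all 3 pairs, where chance gives 25%. DESeq2 called 4 genes: Lyz2 (adjusted p = 7.67e-27), Eps8l1 (log2 -2.03 with edgeR, SE 0.43), H2-M3 (log2 -0.37, SE 0.09) and the mast cell tryptase Tpsb2 (log2 1.23, SE 0.26). Lyz2 also passed without the filter on low counts, with the batch term (0.0200) and with the XX share as a covariate (0.0153), while over all alternatives its adjusted p ran from 7.67e-27 to 1.00. Lyz2 lies on chromosome 10 at 117277331 to 117282321.

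Interferon-stimulated genes were lower in KO than in WT blank cells. All 42 measured were negative (median log2 -0.65, adjusted p = 1.60e-28; 0.414 with an estimated correlation) and 0 passed alone, over all genes or adjusted over the list alone (edgeR). Paired by number, the mean difference of the list was -1.13, 0.05 and -0.94 for numbers 1, 2 and 3, so the 2 libraries numbered 2 did not show it. Irf7, the interferon-induced transcription factor, was at 0.527 (log2 -0.92, SE 0.32), Gbp2 at 0.644 (SE 0.21) and Zbp1 at 0.577 of the WT level. Genes of ER protein handling were slightly lower. Of 39 XBP1 targets 32 were negative (median -0.12, adjusted p = 7.36e-09; 0.141), with the signal peptidase subunit Spcs2 at 0.848 (log2 -0.24, SE 0.08) and Ostc at 0.858. Of 19 ATF6 chaperones 13 were negative (median -0.11, adjusted p = 0.000702; 0.664), with P4hb, a disulphide isomerase, at 0.838. The ATF4 program was higher in 28 of 29 cases (median 0.16, adjusted p = 0.000579; 0.786), with Gars at 1.21-fold and Slc7a5 at 1.33-fold. Paired by number 1, 2 and 3, the mean difference was -0.02, 0.41 and 0.13 for the ATF4 program, so number 1 did not show the rise. It was -0.10, 0.01 and -0.11 for ATF6 chaperones, where number 2 did not show the fall, and -0.14, -0.04 and -0.14 for XBP1 targets. No member of these lists passed. The interferon and XBP1 calls held without any 1 library. The ATF6 call ended without WT blank 2, KO blank 1 or KO blank 3 (0.0816 to 0.191), and the ATF4 call without WT blank 3 (0.102) or KO blank 2 (0.293, mean log2 -0.10).

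Markers of other cells also differed between blank KO and blank WT. Eosinophil and mast cell markers were higher in KO in 11 of 13 cases (median log2 1.11, adjusted p = 4.52e-10; 0.141 with an estimated correlation). Of them 0 passed over all genes and 5 adjusted over the list alone, among them the mast cell proteases Tpsab1 (3.28-fold) and Mcpt4 (2.87-fold). This call held without any 1 library. Resident peritoneal macrophage markers were positive in 16 of 20 cases (median 0.72, adjusted p = 0.000702; 0.786), with Alox15 at 3.47-fold and Vsig4 at 2.46-fold, and the call ended without WT blank 3, KO blank 1 or KO blank 2 (0.0596 to 0.363). Markers of dendritic cells (14 of 15 positive, Clec9a at 1.69-fold, adjusted p = 0.0150), mesothelial cells (14 of 17, Muc16 at 2.53-fold, 0.0140) and B cells (17 of 20, Ebf1 at 1.33-fold, 0.0254) and cell cycle genes (28 of 35, Cdc20 at a log2 difference of 0.68, 0.0193) were higher. The folds of Muc16 and Clec9a rest on few counts. Muc16 was at 0.0742 to 0.104 CPM in blank WT and 0.185 to 0.299 CPM in blank KO. Clec9a was at 0.312 to 0.433 CPM in blank WT and 0.464 to 0.693 CPM in blank KO. T and NK cell markers were lower (17 of 22 negative, Tbx21 at 0.466, 0.0150). With an estimated correlation these 5 had an adjusted p of 0.695 to 0.786. The T and NK call was lost and its mean turned positive without WT blank 2 (mean 0.37, 0.112), and it ended without KO blank 1 (0.514) or KO blank 3 (0.566). The B cell call was lost and its mean turned negative without WT blank 1, WT blank 3 or KO blank 2 (mean -0.17, -0.09 and -0.28; 0.543 to 0.992). The dendritic call ended without WT blank 1, WT blank 3 or KO blank 2 (0.254 to 0.764). The cell cycle and mesothelial calls ended without WT blank 2, WT blank 3, KO blank 1 or KO blank 2 (0.0518 to 0.629), and the cell cycle mean was -0.02 without WT blank 3. With the number of the blank libraries as a block both were lost too (0.0602 and 0.105), and 4 lists were called as higher in KO that were not called without it: neutrophil markers (0.00273, and 0.0762 without the block), inflammatory genes (0.00933 and 0.299), oxidative phosphorylation (0.0325 and 0.0762) and alternative activation (0.0356 and 0.145).

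**Figure D4:**
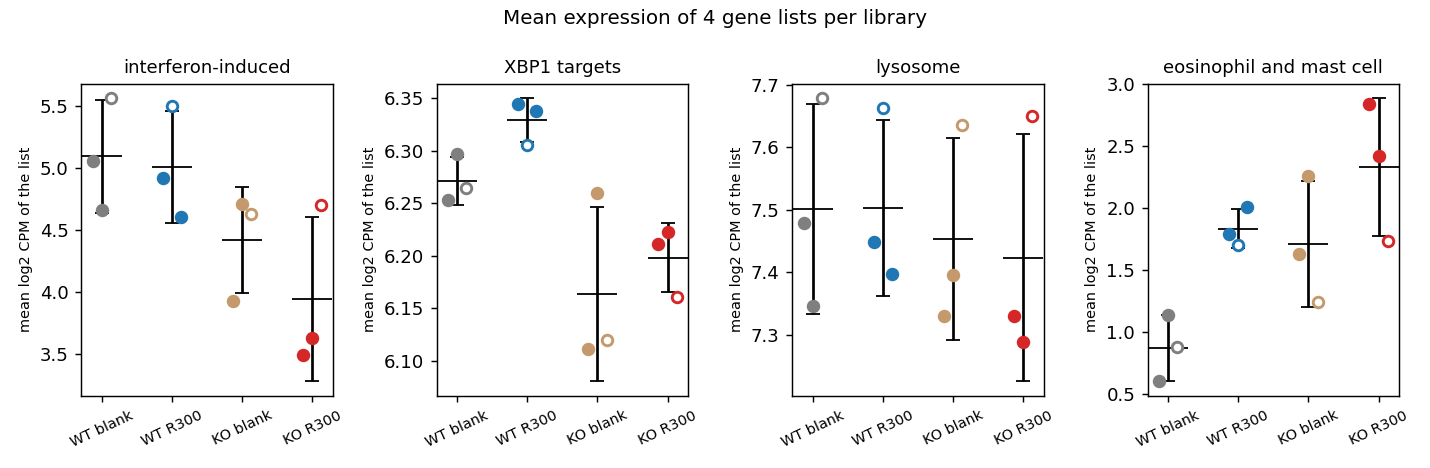
Mean log2 CPM of 4 gene lists (vertical axes) per library in the 4 groups; circles are libraries (open circles without Xist) and bars give the mean ± SD of 3. The interferon list is on average lower in KO than in WT within each kind of library, the difference being -0.87 log2 units with Xist and -0.87 without. The libraries with Xist do not hold the same share of XX cells in WT and KO.

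In R300 cells the differences of KO from WT ran along similar lines. All 42 interferon-stimulated genes were again lower in KO (median log2 -0.98, adjusted p = 6.31e-49; 0.183 with an estimated correlation). Of them 0 passed over all genes and 8 adjusted over the list alone, among them Ifi44 (0.253 of WT, SE 0.47 on the log2 scale), Gbp2 (0.541, SE 0.21) and Bst2, a tether of enveloped viruses (0.679, SE 0.13). Ifi44 was low throughout, at 0.818 to 1.45 CPM in R300 WT and 0.138 to 0.381 CPM in R300 KO. Over blank and R300 libraries together, the mean difference of the interferon list was -0.87 log2 units with Xist and -0.87 without. The estimated share of XX cells in the libraries with Xist differed between the genotypes. Of 39 XBP1 targets 35 were negative (median -0.10, adjusted p = 2.90e-10; 0.176), with Ostc at 0.787 (log2 -0.35, SE 0.08), Spcs2 at 0.831 and Sec61b at a log2 difference of -0.42. Of 19 ATF6 chaperones 15 were negative (median -0.06, adjusted p = 0.00418; 0.874), with P4hb at 0.819 and Pdia6 at 0.806. The Fc receptor and phagocytosis list was slightly higher, 30 of 42 positive (median 0.05, adjusted p = 0.0137; 0.874), with the integrin genes Itgam at 1.52-fold and Itgb2 at 1.13-fold. The interferon and XBP1 calls held without any 1 library. The ATF6 call ended without KO R300 3 (0.131), and the Fc receptor call without WT R300 1, WT R300 3, KO R300 1 or KO R300 3 (0.0722 to 0.647).

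Lyz2 was again lower in KO among R300 cells (log2 -0.82, SE 0.11), with an adjusted p of 0.308. With edgeR 0 genes passed, 324 had an unadjusted p under 0.05 and groups did not overlap for 7.91%, where chance gives 10%. DESeq2 called 14 genes, Lyz2 among them (4.35e-19), and gave no adjusted p for 4176. Without the filter on low counts 1 gene passed, Lyz2, and with both blank libraries numbered 2 set aside 1 gene passed, H2-Q5. Of the 6 apparent pools of mice 4 hold both blank and R300 libraries, so the likeness of these differences to those in blank cells is not independent evidence.

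Eosinophil and mast cell markers were higher in R300 KO than in R300 WT, with 11 of 13 positive (median log2 0.61, adjusted p = 0.000192; 0.623 with an estimated correlation). Of them 2 rose adjusted over the list alone, Tpsab1 (2.98-fold) and Tpsb2 (1.92-fold), and 0 over all genes. Markers of B cells (17 of 20 positive, Ebf1 at 2.08-fold, adjusted p = 0.00416), resident macrophages (16 of 20, Prg4 at a log2 difference of 1.85, 0.00566) and recruited monocytes (13 of 16, Fn1 at 1.78-fold, 0.0137) were higher, and T and NK markers lower (17 of 22 negative, Cd4 at 0.530, 0.0276). With an estimated correlation these 4 had an adjusted p of 0.874. With the XX share as a covariate the means of resident macrophages and recruited monocytes changed sign (-0.18 and -0.07, camera adjusted p = 0.0945 and 0.843). The mean of eosinophils and mast cells was then -0.02, while their camera test still pointed to higher in KO without passing (adjusted p = 0.0945). B cells lost the call with this covariate (0.622). The resident macrophage call ended without WT R300 2, KO R300 1 or KO R300 2 (0.302 to 0.737), the recruited monocyte call without KO R300 1 (0.0722), and the T and NK call without WT R300 2, KO R300 2 or KO R300 3 (0.216 to 0.304).

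Lysosomal genes, which the title of the series concerns, were not called in any comparison. In R300 cells 51 of 71 measured members were lower in KO than in WT (median log2 -0.09, adjusted p = 0.0572), as were 17 of 19 subunits of the V-ATPase, the proton pump that acidifies lysosomes (median -0.09, adjusted p = 0.113). Covariates gave opposite answers, all with the preset correlation. With a batch term for the libraries without Xist both lists were lower in KO (adjusted p = 0.000350 and 0.00585), and with the XX share both were higher (0.000270 and 0.0178). Ctsf was at 1.59-fold and Atp6v0c at 0.773 in that comparison, and none of their members passed. In blank cells 50 of 71 lysosomal genes were lower in KO (median -0.06, adjusted p = 0.115; 0.00887 with the batch term). In the R300 responses the lysosome list had an adjusted p of 0.794 in WT and 0.658 in KO. The smallest adjusted p over the 5 comparisons was 0.216 for substrates of IRE1-dependent decay, 0.125 for autophagy, 0.595 for clock genes and 0.229 for genes described as repressed by NR1D1. Among these, Nfil3, a clock output repressor, rose with R300 4.61-fold in WT (log2 2.21, SE 0.27) and 4.65-fold in KO (log2 2.22, SE 0.27), calls that held without any 1 library. St3gal5, an IRE1 substrate, was at 0.641 in KO with R300 (adjusted p = 0.273) and passed without KO R300 3 (0.0397). Pmp22, another, was at 1.62-fold in WT (0.170).

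Further lists had no call without a block. Their smallest adjusted p over the 5 comparisons was 0.296 for inflammatory genes, 0.742 for cholesterol synthesis, 0.326 for lipid efflux, 0.378 for NADPH oxidase, 0.105 for antigen presentation, 0.565 for erythroid, 0.0762 for neutrophil and 0.0635 for ribosomal protein genes. In the antigen presentation list Ciita alone fell in both responses, and 2 rose adjusted over the list alone in each. For every called list the median, the mean and the camera test had the same sign. Among the others the signs differed in blank cells for V-ATPase, scavenger, lipid efflux and antigen presentation genes. In the WT response they differed for ATF6, lysosome, clock, NR1D1, T and NK and dendritic lists, and in the KO response for ATF6, V-ATPase, autophagy, erythroid, T and NK and dendritic lists. Between R300 cells they differed for ATF4, clock, lipid efflux, platelet, erythroid, dendritic and heat shock lists, and in the interaction for ATF6, clock, NR1D1, alternative activation, lipid efflux, glycolysis and neutrophil lists. Of the called genes named, Tgm2 (21.8% of exonic bases), Crem (8.01%), Cdkn1a (7.68%, a called gene of the KO response) and Cbarp (6.00%) overlap genes on the opposite strand by more than 5%.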

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

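The interferon tests over pools and T or NK cells were chosen after the result was seen, and the splits of the libraries before. A test of the difference of the R300 responses (KO minus WT) picked out 6 lists: interferon (mean log2 -0.3241, adjusted p = 4.70e-07), ATF4 program (-0.1989, 0.0195), cell cycle (-0.2404, 0.0207), eosinophil and mast cell (-0.3635, 0.0207), mesothelial and fibroblast (-0.5214, 0.0195) and mitochondrially encoded transcripts (0.2229, 0.0306). With an estimated correlation each had an adjusted p of 0.991. Each call was lost without some single library. The lowest adjusted p among those losses was 0.0666 (interferon, without KO R300 1) and the highest 0.949 (cell cycle and mesothelial, without WT R300 3).

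Splits of the libraries ask whether chance can be excluded for a count of genes. Of 100 drawn assignments of the R300 label within genotype, all 100 gave as many interaction genes as the real one (0 with edgeR, 95 at an unadjusted p under 0.05; 0 with DESeq2). Any draw does so where the real count is 0, so this decides nothing. The highest other draw gave 4338. It set WT blank 1 with WT R300 1 and 3 apart from the other WT libraries, and KO blank 1 with KO R300 1 and 2 apart from the other KO libraries, which follows the apparent pools and points to a structure of the samples. For 3 libraries against 3 the splits are too few for a share under 0.05. In R300 WT against blank WT 2 of 10 splits gave as many as the real 103. The other gave 514 and set WT blank 1 with WT R300 1 and 3 against the rest, as the apparent pools lie; with the batch term the real split gave 347. In R300 KO against blank KO 1 of 10 did (real 138, highest other 0), in blank KO against blank WT 10 of 10 (0 and 0; 181 genes at an unadjusted p under 0.05, 4 with DESeq2) and in R300 KO against R300 WT 10 of 10 (0 and 0; 324, 14 with DESeq2), the last 2 again fixed by a real count of 0. The blank libraries of WT and KO pair by number, and with a block for the number each of the 4 splits that part all 3 pairs gave 0 genes too (342 at an unadjusted p under 0.05 for the real split, 265 to 489 for the others).

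The interferon list was on average lower in the libraries labelled KO than in WT in blank and in R300 cells, though paired by number the blank differences were -1.13, 0.05 and -0.94, with none for number 2. T or NK cells as the source stay open. The genotype difference of -0.87 (SE 0.28) was -0.92 (SE 0.31) with their list as a covariate, a ratio of 1.052 (dendritic cells were named too at first and dropped after this value was seen), but the list lies near the floor (means of -0.79 to 0.76 log2 CPM per library), and so noisy a covariate decides nothing. Variation between pools of mice stays open too and cannot be told apart from genotype. A list mean as low came up in a share of 0.0125 of 400 assignments of the genotype within treatment, but libraries of 1 apparent pool are not independent, so the bound of 5% set for that test was wrong. Interferon was not alone. The two-sided permutation p was 0.025 for it, 0.01 for XBP1 targets and 0.02 for eosinophil and mast cell markers. It was 0.08 or more for the other lists, all unadjusted. Over the 6 apparent pools, 3 of 20 assignments gave an interferon mean as low, a share of 0.15 where 0.05 is the smallest possible. That test exchanges the pools freely, though libraries also deviated together between genotypes. Loss of Ern1, the difference the design names, stays among the open explanations, untested.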

How the results depend on the processing

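The batch term, the XX share, the 8 libraries with Xist, the blank libraries numbered 2 set aside, the near-identical pairs and the block for the blank libraries alone were chosen after seeing the data. The cause of the changes below was not tested, except that settings with fewer libraries have fewer degrees of freedom. Without 1 library, 3039 gene values kept their side of the threshold and direction, 168 lost and 13 gained a call, and 20 changed sign. Most of the values that stayed belong to genes without a call in the main fit. The 3039 therefore does not measure how stable the calls are. For called lists 479 values stayed, 100 lost the call and 9 changed the direction of the camera test. Under the other alternatives 2779 gene values stayed, again mostly of genes without a call, 99 lost and 83 gained a call, and 12 changed sign. Of the list values 250 stayed, 148 lost the call and 5 changed direction. Where 1 library is left out, the 2 left in its group are assumed to vary like the other groups.

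The number of genes called in R300 WT against blank WT was 355 with DESeq2, 41 with only the groups compared, 347 with the batch term, 307 with the XX share, 242 in the 8 libraries with Xist, 28 with 1 of each near-identical pair and 32 to 135 without 1 library. The 103 genes were all kept with the batch term and with the XX share. In R300 KO against blank KO it was 438, 43, 450, 346, 290 and 34 in the same order, 85 at a fold of at least 2 and 45 to 171 without 1 library. In blank KO against blank WT it was 4 with DESeq2 and 1 without the filter, with the batch term and with the XX share. In R300 KO against R300 WT it was 14 with DESeq2 and 1 without the filter or with the blank libraries numbered 2 set aside. Without 1 library both stayed at 0 with edgeR, as did the difference of responses.

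A replicate block gave 0, 119, 141, 0 and 0 genes in the 5 comparisons. Of 18 correlations between libraries of the same number 10 were over 0.1 (-0.599 to 0.608), and 16 of 36 best matches were of the same number, so the numbers do not pair the libraries over all 4 groups. They pair only blank WT with blank KO. A block for the blank libraries alone gave 0 genes in that comparison. It ended the list calls of cell cycle (0.0602) and mesothelial genes (0.105), brought 4 list calls (neutrophil, inflammatory, oxidative phosphorylation, alternative activation) and changed no other call.

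These values changed sign. In blank KO against blank WT, without 1 library: Cd247 -0.9606 to 0.1024, Igkc -0.1157 to 1.229, Msln -0.3352 to 1.444, Pou2af1 -0.2594 to 1.361, Trbc2 -1.503 to 0.09832, and the lists ATF4 -0.1007 to 0.3403, B cell -0.2775 to 1.027, cell cycle -0.01689 to 0.3542 and T and NK -0.9523 to 0.3659. In R300 KO against blank KO Nr1d1 was -0.05417 with library totals, -0.009469 without the filter, -0.05139 with 1 of each near-identical pair and -0.1253 to 0.1178 without 1 library. In R300 WT against blank WT, without 1 library: Atg9a -0.4854 to 0.0001004, mt-Nd6 -0.4384 to 0.01944 and mitochondrial transcripts -0.4552 to 0.0787; with the blank libraries numbered 2 set aside the last 2 were 0.0192 and 0.07847. In R300 KO against R300 WT, Bhlhe41 was -1.099 to 0.1207 and Xbp1 -0.06859 to 0.2108 without 1 library, and with the XX share Xbp1 was -0.09552, Tlr4 -0.1343, resident macrophages -0.1788, recruited monocytes -0.06705 and eosinophils and mast cells -0.02219.

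For the difference of responses, without 1 library Cry1 was -0.3811 to 0.1131, Ear2 -0.8635 to 0.02441, mt-Rnr1 -0.1258 to 0.6323, ATF4 -0.3437 to 0.09744, cell cycle -0.4744 to 0.03335, mesothelial and fibroblast -1.27 to 0.08994 and mitochondrial transcripts -0.09644 to 0.4302. With the blank libraries numbered 2 set aside Atp6v0e was 0.006945, Atp6v1g1 0.007229, mt-Co3 -0.004664, mt-Nd3 -0.01073, mt-Rnr1 -0.01442, Oas1g 0.04647, interferon 0.005562 and mitochondrial transcripts -0.06644. Depth of 21765600 to 44273700 counts (to 6 digits) limits genes near or under 1 CPM, such as Mir132, Muc16, Clec9a, Fcer2a and Ifi44, more than others.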

Other observations

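The tests of the Lyz2 allele and pool mix, of Xist and of cyclic AMP targets were chosen after the results were seen, and the test of the macrophage share before. Lyz2 was lower in each of the 6 KO libraries than in each of the 6 WT libraries. An exact permutation of genotype within treatment gave p = 0.005 (2 of 400 assignments). That is the smallest value it can give, and the separation of the libraries fixed it. Lyz2 was chosen after its values were seen, and libraries that share a pool are not independent, so this p adds no support. A lower share of macrophages is argued against, since 20 other macrophage transcripts had a median log2 difference of -0.09938 (quartiles -0.25 and 0.02, lowest -0.39) and Lyz2 -0.89. A different mix of mice in the pools cannot be told apart from genotype. Among the libraries without Xist the highest KO value was 0.5411 of the lowest WT value, but these libraries are 1 apparent pool of each genotype, and the values of all 12 libraries already fixed that outcome. An altered Lyz2 allele, as with a Cre gene placed in 1 of the Lyz2 copies, is another candidate explanation that stays open: the ratio of KO to WT means was 0.541 and Lyz1 beside it differed by -0.25, but the labels do not name the Cre driver and the table holds 0 Cre entries.

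Samples labelled male held Xist in 8 of 12 libraries. Xist in male cells that keep their Y transcripts is argued against, since the highest Y-linked sum among libraries with Xist was 0.7919 of the lowest among those without. Cells of female mice in the pools may be the source. Each of the 4 Y-linked genes was lower in every library with Xist than in any without, the largest ratio being 0.8992 (Kdm5d; Ddx3y 0.875, Uty 0.890, Eif2s3y 0.673). The 5 libraries with 431 to 590 CPM of Xist had Y-linked sums of 42.6 to 71.6 CPM, and the 3 with 143 to 169 CPM had 149 to 162 CPM. A correlation over the 8 libraries was looked at first and set aside, because these libraries share pools.

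Crem, the NR4A genes and Vegfa rose with R300, and signalling through cyclic AMP and CREB is a hypothesis for it. A list of 20 CREB targets was tried first and then limited to the 13 outside all other lists. Of these, 11 were positive in WT and 11 in KO, with camera p of 7.264e-05 in WT (0.0318 with an estimated correlation) and 1.13e-05 in KO (0.0212). These p are unadjusted, so they cannot be compared with the adjusted p given for the 36 fixed lists. Of the 13 members, 1 passed in WT and 2 in KO. Pde4d rose in both (log2 2.13, SE 0.38, and 2.95, SE 0.39) and Cdkn1a in KO (1.04, SE 0.20). Ptger4 had the opposite sign (-1.62, SE 0.49, and -1.84, SE 0.50, neither passing). The responses of the list were not shown to differ between genotypes (camera p of 0.357 with limma). The Pde4d call in WT was lost without any WT library except R300 2 and without KO blank 1, KO R300 1 or KO R300 2 (adjusted p 0.0511 to 0.179). The Cdkn1a call in KO was kept only without KO blank 2 or KO R300 3 (otherwise 0.0524 to 0.203), and in WT Cdkn1a passed without KO blank 2 (0.0172) or KO blank 3 (0.0415). The values may reflect such signalling, which was not measured.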
